A study of Mus musculus with 20 samples.

How the data were processed

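RNA of Sca-1 positive mouse kidney cells was measured in 20 libraries of 6 groups: control and roxadustat at day 0 (n = 2 each), day 7 (n = 4 each) and day 21 (n = 4 each). The labels describe a non-stranded mRNA library prepared from Trizol extracts. The deposited files hold raw counts per Ensembl gene for each library, and the authors list bcl2fastq (version not given), STAR 2.5.2a, featureCounts 1.5.0-p1 and the mm10 genome for making them. The annotation release is not given. All files list the same 47729 genes, of which 47224 were matched to a symbol and to coordinates in GENCODE M21 (GRCm38), a release that may differ from that of the authors. The labels give 1 protocol text for all libraries, and groups were taken from the time and treatment labels. No sample, file or column was left out.

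Total counts were 19.56 and 19.45 M (mega counts) in control and 18.71 and 15.97 M in roxadustat libraries at day 0. At day 7 they were 14.63, 16.93, 17.65 and 17.69 M in control and 19.03, 19.04, 16.73 and 19.9 M in roxadustat libraries, and at day 21 17.66, 17.91, 13.68 and 15.79 M in control and 12.82, 15.17, 8.502 and 17.59 M in roxadustat libraries. The biological coefficient of variation within groups was 16.2% and 8.99% in control and roxadustat cells at day 0, 4.06% and 6.49% at day 7, and 9.12% and 7.19% at day 21.

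All computation was done in R 4.3.3. Counts were fitted in 1 model of all 20 libraries with edgeR 4.0.16 (filterByExpr, TMM scaling, robust dispersions, quasi-likelihood F test, Benjamini-Hochberg adjustment, adjusted p threshold of 0.05), with 18731 genes tested. Levels are CPM scaled by TMM, given as mean ± SD of the libraries of a group, and log2 fold changes are those of the fit ± SE. The SE is the absolute log2 fold change divided by the square root of its F. It thus restates the test and draws on the spread in all libraries. The comparisons were roxadustat against control at each time, day 7 against day 0 and day 21 against day 7 in each arm, and the interactions of these. A fold against a group without counts is computed against a floor of 3 counts over the group. With 1 to 3 counts in a group the ratio of counts is given with an exact 95% counting interval.

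For gene groups, 31 lists of genes were written before the data were examined. Each was tested with camera (limma 3.58.1, preset correlation between genes of 0.01), with the adjustment over the lists of a comparison. Alternatives were a correlation estimated from the data and fry. Members called are also counted with the adjustment over the list alone. The genes to be named were set by a rule fixed at the same time. It takes the 8 largest rises and falls with at least 5 CPM in the higher group and no overlap between libraries, up to 4 members per list by p, 10 genes in every comparison and the 5 smallest p of each interaction. The text leaves out some that the rule takes, mostly genes with 1 to 3 counts in a group and genes with close paralogs, and some genes are not reported here because they are withheld for evaluation. Genes named as the exceptions of a list, mt-Rnr2, Rn7sk, Rpph1, Kap, and the partner and neighbour genes of H2-Ab1 fall outside the rule and were chosen after their values were seen.

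Alternatives were DESeq2's size factors, library size alone and the upper quartile for scaling, no filter (34124 genes) and a mean of at least 1 CPM (14656 genes), the replicate number as a block, DESeq2 1.42.0 and limma voom, only the groups compared, an adjusted p threshold of 0.01, a fold of at least 2, and leaving out each library in turn. In the last of these a lone day 0 library is assumed to vary like the other groups. The steps were tested on simulated data with the depth of these libraries and 200 changed genes per comparison. These changed up or down at random and were far fewer than the 8926 and 11781 genes called at day 7 and day 21. The rates below may thus not hold for the real comparisons, and the choice of scaling was not tested by them. Each gene had 1 spread in all groups, estimated over the 20 libraries. The larger spread of control cells at day 0 (16.2%) was not simulated, so the rates for day 0 may be too favourable. At day 0 edgeR recovered 62.7%, 85.1% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, and 8.38% of its calls were false. At day 7 it recovered 85.1%, 95.5% and 100% with 6.03% false calls, and at day 21 77.6%, 88.1% and 100% with 3.8% false calls. Of the calls of limma voom at day 0 23.8% were false, and of those of DESeq2 9.5%.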

Results

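Kidney cells that carry Sca-1, a surface protein of stem and progenitor cells encoded by Ly6a, were isolated from mice with magnetic beads, and their RNA was sequenced in 20 libraries. The question of the series is how erythropoietin-producing cells of the renal interstitium react to roxadustat. This anemia drug blocks the prolyl hydroxylases that mark hypoxia-inducible factor (HIF) for degradation. Day 0 libraries came from cells straight from the kidney, 2 from control mice and 2 from mice injected with roxadustat for 7 days (33 mg/kg). The other libraries came from cells cultured in 20% oxygen for 7 or 21 days, with 4 control and 4 roxadustat libraries at each time. The labels do not say whether the cultured roxadustat cells came from injected mice or had roxadustat added to their medium. They also do not say whether replicates are separate animals or cultures, so every p measures only the spread between these libraries.

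Epo, the gene of erythropoietin (ENSMUSG00000029711), had 1 count in replicate 2 of control and 1 in replicate 2 of roxadustat cells at day 7 and 0 in every other library. Intervals and floors in this text cover counting error only. A floor of 3 counts over a group is 0.0364 to 0.106 CPM. Epo lay under this floor in every group, so no difference in it could be resolved at this depth. Transcripts of tubule cells were abundant in fresh control cells after the sort, with Umod, the uromodulin gene of the loop of Henle, at 10420 ± 1940 CPM and the proximal tubule receptor Lrp2 at 8741 ± 565 CPM (mean ± SD, n = 2).

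Freshly isolated cells of roxadustat-injected mice, set against those of control mice to see what the injections changed in the kidney, had more transcripts of collagens and other matrix proteins, of macrophages, and of HIF targets and glycolysis. Postn, periostin, a matrix protein of activated fibroblasts (chromosome 3, 54361109 to 54391037 on GRCm38), was at 132 ± 66.2 CPM in roxadustat and 8.79 ± 0.409 CPM in control cells (mean ± SD, n = 2 each). Its fitted log2 fold change was 3.90 ± 0.25 (SE, edgeR, adjusted p = 4.41e-08), and 3.27 without roxadustat replicate 2. The fibrillar collagen gene Col3a1 (chromosome 1, 45311538 to 45349706) rose from 143 ± 39.9 to 1254 ± 475 CPM, by 3.13 ± 0.22 on the log2 scale (adjusted p = 9.87e-08). The list tests for day 0 below draw on the spread in all 20 libraries, and none was run on the day 0 libraries alone. Of 32 tested genes of extracellular matrix and myofibroblasts, 17 were higher and 1, the protease inhibitor gene Timp3, was lower (18 and 2 adjusted over the list alone; camera adjusted p = 1.23e-35). The call of Timp3 ended without control replicate 2 (adjusted p = 0.245) and without roxadustat replicate 1 (0.119), and that of the list was kept without each of the 4 libraries. Of 22 interstitial fibroblast markers 11 were higher and none lower (12 higher adjusted over the list alone; adjusted p = 1.15e-16), among them Col1a1 (5.77-fold), Col1a2 (6.03-fold) and the proteoglycan gene Lum (5.76-fold). Without control replicate 1 the count was 6 and the list's adjusted p = 0.0676 with an estimated correlation.

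Roxadustat cells at day 0 also had more transcripts of HIF targets outside glycolysis, with 12 of 30 higher, 2 lower and 16 not called (15 and 2 adjusted over the list alone; adjusted p = 1.02e-13). Car9, a carbonic anhydrase and HIF target (chromosome 4, 43506966 to 43513729), was at 23.5 ± 3.42 against 4.55 ± 0.645 CPM (n = 2 each), a log2 fold change of 2.37 ± 0.16 (edgeR adjusted p = 9.93e-11). P4ha1, a subunit of collagen prolyl hydroxylase, was 2.45-fold, the HIF target Ankrd37 2.49-fold and the HIF prolyl hydroxylase gene Egln3 1.71-fold higher, the latter with adjusted p = 0.0706 without roxadustat replicate 1. The 2 lower HIF targets were Pdgfb, a growth factor that recruits pericytes (1.83-fold lower), and the repressor gene Bhlhe40. Of 22 genes of glycolysis and glucose uptake 10 were higher and 3 lower (11 and 4 adjusted over the list alone; adjusted p = 1.49e-14), with Pfkl (phosphofructokinase) 2.68-fold and Ldha (lactate dehydrogenase) 2.23-fold higher. The angiogenic factor gene Vegfa (350 ± 19.4 against 312 ± 6.81 CPM, adjusted p = 0.149) and the glucose transporter gene Slc2a1 (82.7 ± 2.24 against 98.5 ± 3.5 CPM, adjusted p = 0.0627) were not called. Vegfa was called higher after scaling by library size alone (adjusted p = 0.0494), and Slc2a1 lower by DESeq2 (adjusted p = 0.0228). Hmox1, heme oxygenase, fell from 216 ± 8.35 to 60.8 ± 2.97 CPM (3.56-fold, adjusted p = 4.78e-09).

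Macrophage and dendritic cell markers were higher in the fresh roxadustat cells, 11 of 22 with none lower (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.73e-18). Lyz2, lysozyme, was at 55.8 ± 7.4 against 13.8 ± 2.21 CPM (4.04-fold; edgeR adjusted p = 4.18e-12), and the complement gene C1qa was 2.95-fold higher. The chemokine gene Ccl6 rose 6.62-fold. Endothelial markers were lower, 15 of 22 with none higher (19 lower adjusted over the list alone; adjusted p = 1.57e-22), including the VEGF receptor genes Kdr and Flt1, 1.77-fold and 1.76-fold. General epithelial markers were also lower, 11 of 21 (12 adjusted over the list alone; adjusted p = 1.55e-07), as were 9 of 21 markers of loop, distal tubule and collecting duct (11 adjusted over the list alone; adjusted p = 1.05e-10), with the water channel gene Aqp2 2.51-fold lower. The adjusted p of the distal list was 0.0679 with an estimated correlation without control replicate 1. Of 22 proximal tubule markers 1 was higher and 2 lower (1 and 2 adjusted over the list alone; adjusted p = 0.746). Genes of cholesterol synthesis and SREBP2 targets fell in 12 of 25 cases (18 adjusted over the list alone; adjusted p = 2.07e-15). Immediate early and heat shock genes, which also respond to tissue dissociation, were lower in 12 of 28 cases with 1 higher (12 and 1 adjusted over the list alone; adjusted p = 2.57e-06), and the list stayed called without each of the 4 libraries. Without roxadustat replicate 1 there were 7 macrophage, 5 endothelial and 3 epithelial calls.

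Ly6a, the gene of the sorted protein (chromosome 15, 74994877 to 74998031), was at 691 ± 33.3 CPM in roxadustat and 523 ± 38.4 CPM in control cells at day 0 (1.32-fold; edgeR adjusted p = 0.00415), with adjusted p = 0.0528 without roxadustat replicate 2. Nt5e, the ecto-nucleotidase CD73 of interstitial fibroblasts and some tubule cells, was 1.24-fold higher (adjusted p = 0.0294). That call ended without control replicate 1 (adjusted p = 0.209) and without roxadustat replicate 1 (0.558). The PDGF receptor genes of mesenchymal cells were not called: Pdgfra was at 24.3 ± 2.47 against 18.2 ± 13.3 CPM (adjusted p = 0.517) and Pdgfrb at 5.03 ± 1.49 against 6.18 ± 0.171 CPM (adjusted p = 0.313). Pdgfra was called higher without control replicate 2 (log2 fold change 1.46, adjusted p = 2.42e-08) and with no filter (0.39, adjusted p = 0.0309), and Pdgfrb lower without roxadustat replicate 2 (-0.64, adjusted p = 0.0451). Across 18731 tested genes edgeR called 511 higher and 769 lower in roxadustat cells at day 0, and after scaling by library size alone 699 higher and 524 lower. The day 0 calls, of genes and of lists, draw on the spread in all 20 libraries. Fitted to the 4 day 0 libraries alone edgeR called 23 genes, 22 of them among the 1280. Of the genes named here for day 0, Car9, P4ha1, Pfkl, Ldha, Hmox1, Pdgfb, Pdk1, Lyz2 and Ccl6 kept their call in that fit. The other 15 calls did not, among them Postn (log2 fold change 3.92, adjusted p = 0.141) and Col3a1 (3.15, adjusted p = 0.091), whose fold changes hardly moved.

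After 7 days of culture, roxadustat cells differed from control cells in HIF targets and glycolysis and in cell cycle, macrophage and epithelial genes, among others. Slc16a3, the lactate exporter MCT4 (chromosome 11, 120948480 to 120960868), was at 482 ± 22.5 CPM with roxadustat and 3.77 ± 0.417 CPM without (mean ± SD, n = 4 each), a log2 fold change of 7.00 ± 0.09 (edgeR adjusted p = 2.07e-28). All 30 tested HIF targets were called, 29 higher (29 adjusted over the list alone; camera adjusted p = 4.59e-88), the lower one being the cytokinesis gene Anln. All 22 genes of glycolysis and glucose uptake were called as well, 20 higher and Pfkfb4 and Eno2 lower (20 and 2 adjusted over the list alone; adjusted p = 1.68e-91). Vegfa rose from 62.7 ± 1.62 to 334 ± 15.0 CPM (5.34-fold), Egln3 21.2-fold, Slc2a1 5.14-fold, Car9 12.9-fold, and Pdk1, the kinase that closes pyruvate dehydrogenase, 33.9-fold. Ankrd37, a HIF target with 22.7% of its exon bases shared with Lrp2bp, rose 26.0-fold. Ndufa4l2 and Mgarp, mitochondrial proteins, rose 87.2-fold and 342-fold, and Hmox1 rose 7.26-fold to 1463 ± 34.5 CPM. The oxygen-sensing genes went both ways, with 5 of 10 higher and 4 lower (5 and 4 adjusted over the list alone; adjusted p = 0.00255, and adjusted p = 0.0786 with an estimated correlation). Egln1 rose 4.42-fold while Hif1a, the subunit of HIF that the hydroxylases act on, fell 1.93-fold.

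Cell cycle genes were lower with roxadustat at day 7, 37 of 38 with none higher (37 adjusted over the list alone; camera adjusted p = 7.18e-43). The helicase subunit gene Mcm6 fell from 78.5 ± 1.96 to 21.7 ± 0.847 CPM (n = 4 each, edgeR adjusted p = 5.9e-19), and the centromere histone gene Cenpa fell 3.55-fold. Of the 22 macrophage and dendritic cell markers 17 were lower and 2 higher (17 and 2 adjusted over the list alone; adjusted p = 1.37e-21). Lyz2 was at 6.003 ± 0.239 against 242 ± 2.43 CPM (40.2-fold lower), and C1qa was 30.8-fold lower. The 2 higher ones were Cd14 and H2-Ab1, an MHC class II gene at 28.0 ± 2.37 against 0.130 ± 0.061 CPM. The call of Cd14 ended without control replicate 4 (edgeR adjusted p = 0.0562) and without roxadustat replicate 1 (0.0503).

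General epithelial markers were higher with roxadustat at day 7, 18 of 21 with none lower (19 adjusted over the list alone; camera adjusted p = 1.38e-12). The kidney cadherin gene Cdh16 rose from 84.7 ± 3.75 to 207 ± 8.36 CPM (n = 4 each), and Pax8, a transcription factor of kidney epithelium, rose 2.40-fold. Of 22 proximal tubule markers 6 were higher, Lrp2 2.67-fold, and none lower (6 adjusted over the list alone; adjusted p = 0.00255, and adjusted p = 0.412 with an estimated correlation). The mean log2 CPM of this list was 0.54 and 1.51 in roxadustat replicates 1 and 2 but -0.20 and -0.08 in 3 and 4, against 0.0023 to 0.14 in control libraries, while Lrp2 was at 163 to 176 CPM in all 4. Markers of pericytes and smooth muscle were lower, 9 of 15 with 1 higher (9 and 1 adjusted over the list alone; adjusted p = 4.6e-12), with the smooth muscle actin gene Actg2 7.81-fold and the pericyte proteoglycan gene Cspg4 8.73-fold lower. Fibroblast markers were lower in 13 of 22 cases with 1 higher (14 and 1 adjusted over the list alone; adjusted p = 8.01e-05, and adjusted p = 0.172 with an estimated correlation). Matrix genes were lower in 22 of 32 cases with 4 higher (22 and 4 adjusted over the list alone; adjusted p = 4.2e-05, and adjusted p = 0.222 with an estimated correlation). Pdgfrb fell from 255 ± 9.01 to 115 ± 9.12 CPM, Pdgfra from 13.02 ± 1.08 to 5.50 ± 0.354 CPM, and Ly6a rose from 163 ± 6.58 to 502 ± 23.3 CPM. Nt5e was not called (331 ± 19.8 against 343 ± 9.36 CPM, edgeR adjusted p = 0.555). The mitochondrial ribosomal RNA mt-Rnr2 took 0.48% of counts with roxadustat and 1.27% without at day 7, and 0.572% and 1.41% at day 21. Over all tested genes 4507 were higher and 4419 lower at day 7, 2485 of them at least 2-fold. Scaling by library size alone gave 5366 higher and 3648 lower, and DESeq2's size factors 4036 and 4902.

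**Figure D1:**
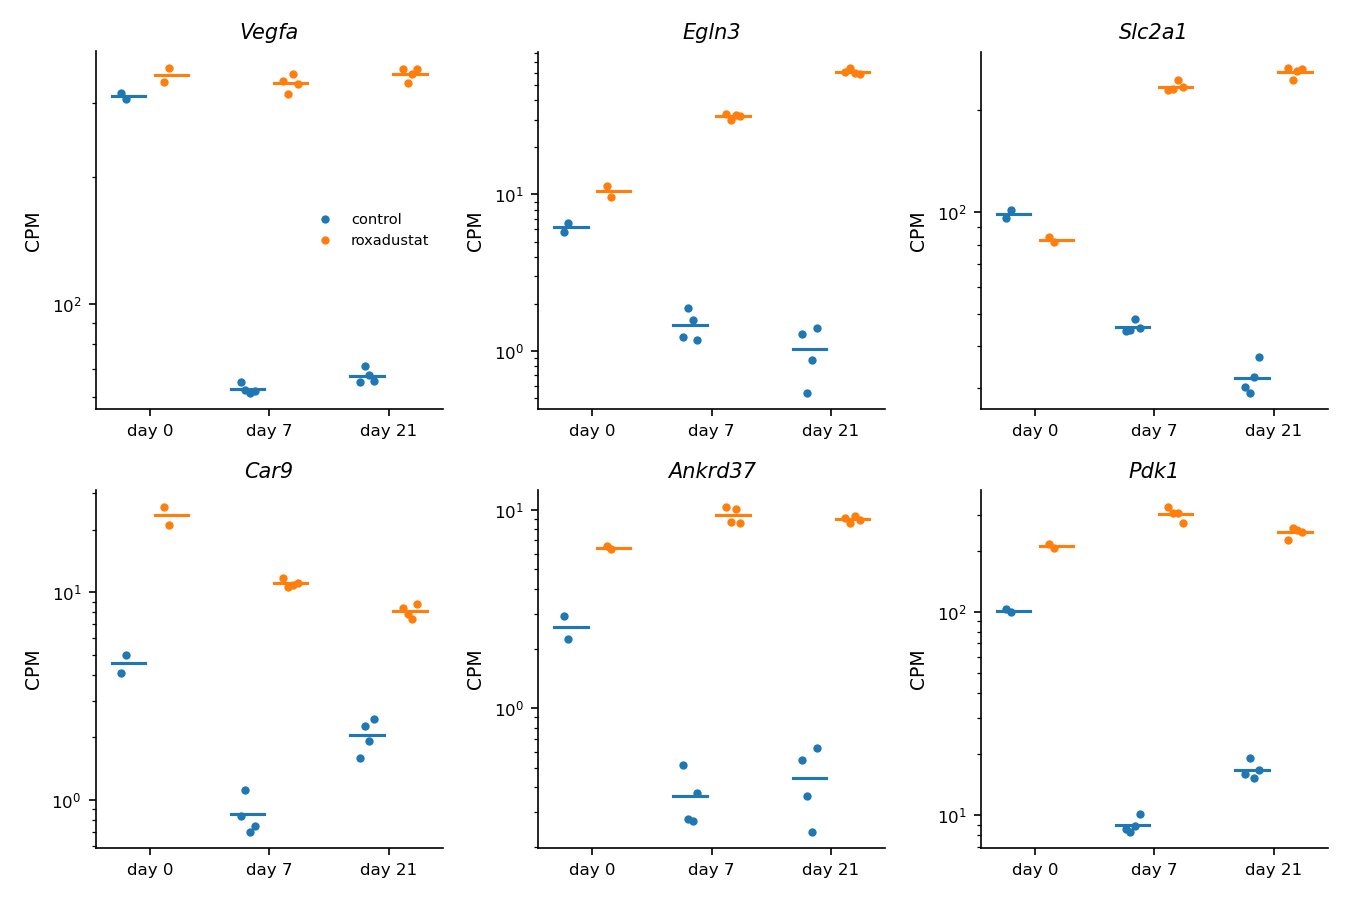
Expression of 6 HIF targets in each library at day 0, day 7 and day 21, in CPM on a logarithmic axis; points are libraries, bars are group means, blue is control and orange roxadustat. At day 7 and day 21 every roxadustat library lies above every control library for each gene, as with Vegfa at 334 and 62.7 CPM on average at day 7.

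At day 21 the roxadustat cells had high levels of kidney epithelial genes and low levels of fibroblast and matrix genes compared with control cells. The 4 control libraries of this day lie in 2 close pairs, replicates 1 and 2 and replicates 3 and 4. They may be fewer than 4 independent units, while the SD, SE and p of comparisons with them treat them as 4. All 21 general epithelial markers were higher (21 adjusted over the list alone; camera adjusted p = 1.04e-21), with a median log2 fold change of 5.18. Cdh16 (chromosome 8, 104601911 to 104624396) was at 115 ± 2.94 CPM with roxadustat and 2.82 ± 0.38 CPM without (mean ± SD, n = 4 each), a log2 fold change of 5.33 ± 0.08 (edgeR adjusted p = 1.11e-27). Pax8 rose 16.8-fold and the tight junction gene Cldn4 81.9-fold. Hnf4a, a transcription factor of proximal tubule cells, was at 7.70 ± 0.373 CPM and had no count in control cells, so it was at least 153-fold higher against a floor of 3 counts over the group. Of 22 proximal tubule markers 8 were higher and none lower (8 adjusted over the list alone; adjusted p = 7.89e-06, and adjusted p = 0.196 with an estimated correlation). Lrp2 was at 174 ± 3.93 against 4.19 ± 1.17 CPM, Ggt1, a brush border transpeptidase, was 167-fold and the water channel gene Aqp1 25.8-fold higher. The loop, distal tubule and collecting duct list had 3 higher and 3 lower of 21 (3 and 3 adjusted over the list alone; adjusted p = 0.787).

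Fibroblast markers were lower with roxadustat at day 21, 19 of 22 with 2 higher (19 and 2 adjusted over the list alone; camera adjusted p = 3.6e-16). A rise or fall at 1 day is from control to roxadustat cells, not over time. At day 7 Pdgfra was at 5.1 to 5.91 CPM in roxadustat libraries and at 11.7 to 13.9 CPM in control libraries. At day 21 the following changes were found. Pdgfra fell from 153 ± 2.23 to 4.42 ± 0.528 CPM (n = 4 each; 34.4-fold, edgeR adjusted p = 1.01e-11), Pdgfrb from 739 ± 43.0 to 120 ± 4.74 CPM (6.18-fold), the matrix protein gene Dpt 121-fold and the fibroblast protease gene Fap 28.3-fold. The 2 higher ones were Foxd1, a transcription factor of stromal progenitors, and Nt5e, which rose from 13.8 ± 0.835 to 412 ± 18.0 CPM. Of the 32 matrix genes 26 were lower and 4 higher (26 and 5 adjusted over the list alone; adjusted p = 2.76e-14), with the collagen gene Col12a1 falling from 10490 ± 778 to 1595 ± 40.7 CPM. Ccn2, Tnc and Thbs1 were among the higher ones. Thy1, a surface marker of mesenchymal cells, fell 27.8-fold and Ly6a rose 2.84-fold, to 506 ± 25.8 CPM. Mesenchymal stromal cell markers as a list went both ways, 6 of 15 higher and 8 lower (6 and 8 adjusted over the list alone; adjusted p = 0.787). The growth factor gene Ptn fell 133-fold, Sfrp1, which binds Wnt proteins, 119-fold, and the growth factor carrier gene Igfbp3 23.9-fold, from 2130 ± 71.5 CPM.

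HIF targets stayed high with roxadustat at day 21, 29 of 30 higher and Loxl2 lower (29 and 1 adjusted over the list alone; camera adjusted p = 6.07e-32). The call of Loxl2 ended after scaling by library size alone (edgeR adjusted p = 0.137). In addition 19 of 22 genes of glycolysis and glucose uptake were higher with 3 lower (19 and 3 adjusted over the list alone; adjusted p = 2.93e-28). Vegfa was at 352 ± 12.9 against 67.3 ± 2.67 CPM (n = 4 each; edgeR adjusted p = 1.46e-24), Slc16a3 was 152-fold, Egln3 58.9-fold, Ankrd37 19.4-fold, Slc2a1 8.06-fold and Car9 3.94-fold higher. Targets of ATF4, the transcription factor of amino acid stress, were higher in 21 of 25 cases with 3 lower (21 and 3 adjusted over the list alone; adjusted p = 2.55e-06), the cystine transporter gene Slc7a11 14.2-fold. The stress cytokine gene Gdf15 rose 25.7-fold, and Spp1, osteopontin, from 694 ± 79.4 to 20580 ± 1660 CPM. Interferon response genes were lower in 28 of 31 cases with 1 higher (28 and 1 adjusted over the list alone; adjusted p = 5.12e-08, and adjusted p = 0.153 with an estimated correlation), and cholesterol synthesis genes in 21 of 25 with 2 higher (21 and 2 adjusted over the list alone; adjusted p = 0.000106, and adjusted p = 0.153 with an estimated correlation). The mean log2 CPM of the interferon list was 1.73 to 2.01 at day 7 and 3.28 to 3.44 at day 21 in control libraries. With roxadustat it was 1.36 to 1.5 and 1.36 to 1.58. The ATF4 list was at 6.18 to 6.2, then 5.42 to 5.52 in control libraries. It was at 6.16 to 6.24, then 6.25 to 6.32 with roxadustat. On both lists control cells moved more between these days than roxadustat cells. Macrophage markers were lower in 17 of 22 cases with 2 higher (17 and 2 adjusted over the list alone; adjusted p = 1.64e-05, and adjusted p = 0.153 with an estimated correlation). Lyz2 was 41.9-fold lower and H2-Ab1, with no count in control cells, at least 433-fold higher. Over all tested genes 5616 were higher and 6165 lower, 5278 of them at least 2-fold. Scaling by library size alone moved the median log2 fold change of all genes by 0.34 and gave 9372 higher and 3549 lower.

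The changes with roxadustat at day 7 and day 21 shared many genes. Called at both days in the same direction were 2950 higher genes, where independent lists would share 1351.3, and 2937 lower genes, where 1454.4 would be shared (Fisher's exact test across genes, odds ratios of 8.21 and 6.80; genes are not independent replicates). Slc16a3, Egln3, Vegfa, Cdh16 and H2-Ab1 were among the shared rises and Lyz2, Pdgfra, Pdgfrb and Hif1a among the shared falls. Another 1057 genes were called in opposite directions, fewer than independent lists would give. Of the 1280 genes called at day 0, 410 were called the same way at day 7 and 466 the opposite way, where independent lists would give 304.4 and 305.6. Car9, Egln3 and Pdk1 were higher at all 3 times, and Lyz2 was higher at day 0 and lower at day 7 and day 21.

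**Figure D2:**
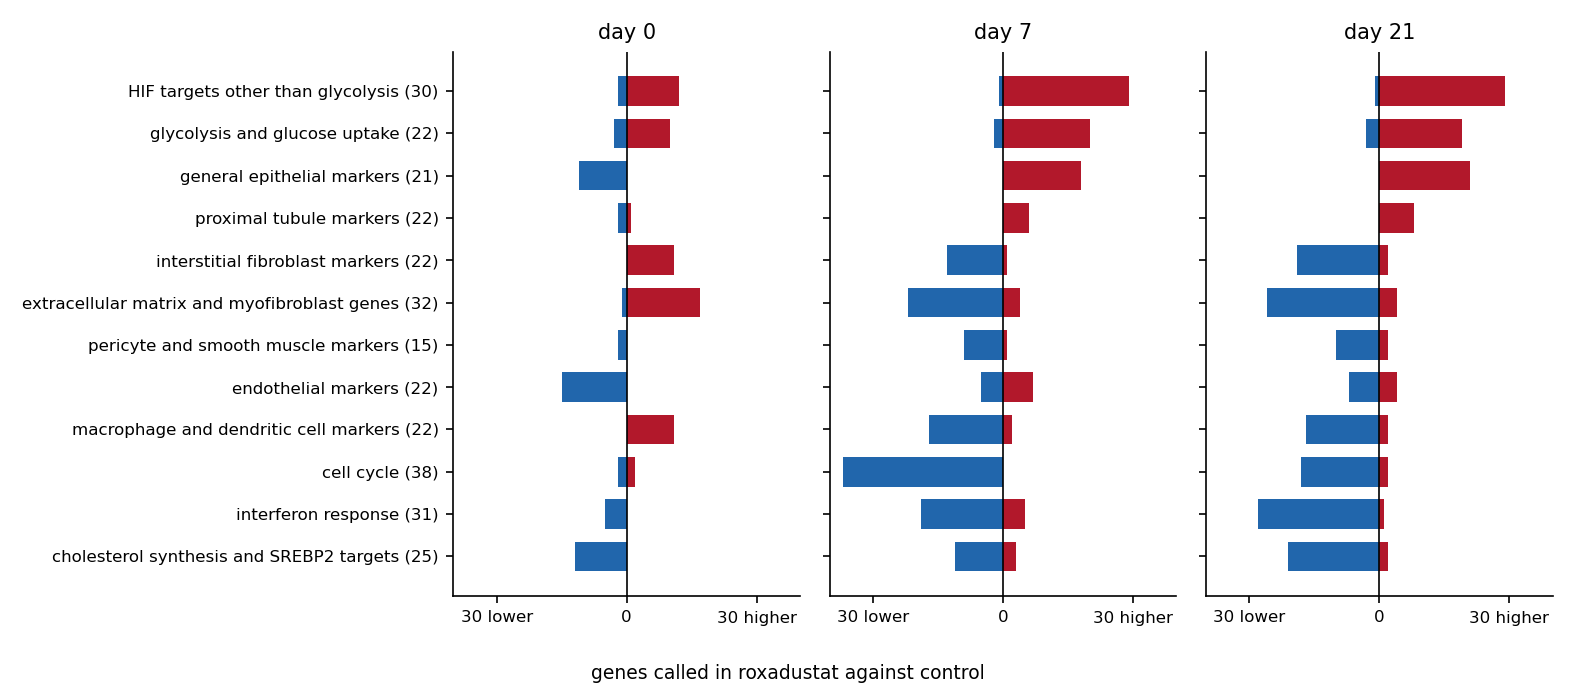
Number of members called higher (right of 0) and lower (left of 0) in roxadustat against control cells for 12 gene lists at day 0, day 7 and day 21 (bars; edgeR, adjusted p threshold 0.05; the number tested stands beside each list). Epithelial markers have 11 lower at day 0, 18 higher at day 7 and 21 higher at day 21, and macrophage markers 11 higher at day 0 and 17 lower at both later days.

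Control cells after 7 days of culture were set against fresh control cells to see what culture alone did, and they had lost most tubule transcripts and gained those of dividing mesenchymal cells. Umod fell from 10420 ± 1940 CPM (n = 2) to 0.954 ± 0.267 CPM (n = 4; edgeR adjusted p = 2.23e-12), although 19.5% of its exon bases are shared with Gm44588, and Lrp2 from 8741 ± 565 to 63.7 ± 1.93 CPM. All 22 proximal tubule markers were lower (22 adjusted over the list alone; camera adjusted p = 3.8e-25), as were all 21 markers of loop, distal tubule and collecting duct (21 adjusted over the list alone; adjusted p = 4.35e-17). Endothelial markers were lower in 19 of 22 cases with Flt1 higher (19 and 1 adjusted over the list alone; adjusted p = 6.4e-06), the adhesion gene Pecam1 210-fold. Vim, vimentin of mesenchymal cells (chromosome 2, 13573927 to 13582826), rose from 47.6 ± 4.76 to 4889 ± 81.1 CPM, a log2 fold change of 6.68 ± 0.14 (adjusted p = 4.97e-25), and Pdgfrb from 6.18 ± 0.171 to 255 ± 9.01 CPM (41.3-fold). Of 15 pericyte and smooth muscle markers 10 were higher and 4 lower (10 and 4 adjusted over the list alone; adjusted p = 2.75e-05), with the muscle filament gene Des 174-fold and the contractile gene Cnn1 469-fold higher. Matrix genes were higher in 27 of 32 cases with 4 lower (27 and 4 adjusted over the list alone; adjusted p = 1.38e-18). Fibroblast markers were higher in 16 of 22 cases with 5 lower (16 and 5 adjusted over the list alone; adjusted p = 7.24e-05, and adjusted p = 0.153 with an estimated correlation).

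All 38 cell cycle genes were higher in control cells at day 7 than at day 0 (38 adjusted over the list alone; camera adjusted p = 3.78e-14), Rrm1, a subunit of ribonucleotide reductase, 13.4-fold. Of 23 p53 and senescence genes 17 were higher and 4 lower (17 and 4 adjusted over the list alone; adjusted p = 3.83e-08). Cdkn2a, which encodes the cell cycle inhibitors p16 and p19, was at 163 ± 13.5 CPM (n = 4) and 2500-fold higher (95% counting interval 691 to 20600, from 2 counts at day 0). Immediate early and heat shock genes were lower in 24 of 28 cases with 1 higher (24 and 1 adjusted over the list alone; adjusted p = 7.85e-24), Fos falling from 2611 ± 157 (n = 2) to 6.78 ± 0.178 CPM. Nuclear genes of oxidative phosphorylation were lower in 40 of 41 cases (40 adjusted over the list alone; adjusted p = 2.11e-13, and adjusted p = 0.174 with an estimated correlation). In the same comparison mt-Rnr2 went from 9.18% of counts to 1.27%. Vegfa fell 4.97-fold, Slc2a1 2.16-fold, Car9 5.30-fold, Ankrd37 7.14-fold, Egln3 4.15-fold and Ly6a 3.20-fold, while Nt5e rose 1.73-fold (edgeR adjusted p = 5.61e-10). Pdgfra was not called (adjusted p = 0.112), and its 2 day 0 libraries lie apart. Without control day 0 replicate 1 it was called lower at day 7 (log2 fold change -1.08, adjusted p = 3.02e-10), and without replicate 2 higher (0.56, adjusted p = 0.000516). With no filter it was called lower (-0.44, adjusted p = 0.000112). Over all tested genes 6925 were higher and 7401 lower. Scaling by library size alone moved the median log2 fold change by 0.42 and gave 9073 higher and 5645 lower, and the upper quartile moved the median by 0.11.

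Between day 7 and day 21 control cells gained fibroblast, matrix and interferon genes and lost epithelial and cell cycle genes. Lum (chromosome 10, 97565128 to 97572703) rose from 0.703 ± 0.155 to 636 ± 77.9 CPM (mean ± SD, n = 4 each), a log2 fold change of 9.79 ± 0.20 (edgeR adjusted p = 1.13e-17). Cxcl12, a chemokine of stromal cells, rose 19.4-fold, Pdgfra 11.7-fold, Ptn 149-fold, Col12a1 13.2-fold and Epas1, which encodes HIF-2 alpha, 11.4-fold. Of 22 fibroblast markers 17 were higher and 4 lower (17 and 4 adjusted over the list alone; camera adjusted p = 1.6e-08, and adjusted p = 0.0839 with an estimated correlation). Matrix genes were higher in 23 of 32 cases with 5 lower (24 and 6 adjusted over the list alone; adjusted p = 1.45e-08, and adjusted p = 0.154 with an estimated correlation), and interferon response genes in 27 of 31 with none lower (27 adjusted over the list alone; adjusted p = 9.59e-08, and adjusted p = 0.195 with an estimated correlation). General epithelial markers were lower in 19 of 21 cases with Esrp2, a splicing factor of epithelial cells, higher (19 and 1 adjusted over the list alone; adjusted p = 4.82e-16). The call of Esrp2, whose groups overlap, ended without day 7 replicate 1 (edgeR adjusted p = 0.0745) or 3 (0.0615) and without day 21 replicate 2 (0.0528) or 4 (0.092), as well as after scaling by library size alone (0.361) and with limma voom (0.0515). Havcr1, the kidney injury molecule of damaged proximal tubules, fell from 807 ± 28.4 to 9.26 ± 1.11 CPM, and Nt5e 24.7-fold. Cell cycle genes were lower in 35 of 38 cases with 2 higher (35 and 2 adjusted over the list alone; adjusted p = 7.17e-20), the checkpoint kinase gene Bub1 5.72-fold. Immediate early and heat shock genes were higher in 15 of 28 cases with 8 lower (15 and 8 adjusted over the list alone; adjusted p = 9.92e-07), Fos 27.8-fold. Targets of ATF4 were lower in 19 of 25 cases with 3 higher (20 and 3 adjusted over the list alone; adjusted p = 7.96e-07). Pdgfrb rose 2.89-fold and Car9 2.41-fold, and Slc2a1 fell 1.42-fold, while Vegfa and Ly6a were not called (edgeR adjusted p = 0.0739 and 0.0794). Ly6a was called higher without day 21 replicate 3 (adjusted p = 0.0283) or 4 (0.0235), with a mean of at least 1 CPM (0.0196) and with only the groups compared (0.0483). Vegfa was called higher after scaling by the upper quartile (adjusted p = 0.0492), with a mean of at least 1 CPM (0.0113) and with only the groups compared (0.0313). Over all tested genes 6456 were higher and 6421 lower, while scaling by library size alone moved the median by -0.19 and gave 5063 higher and 8172 lower.

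Roxadustat cells changed in many of the same gene groups between day 0 and day 7, with all 22 proximal tubule markers lower (22 adjusted over the list alone; camera adjusted p = 7.21e-27) and 24 of 32 matrix genes higher with 7 lower (24 and 7 adjusted over the list alone; adjusted p = 8.73e-13). HIF targets were higher in 21 of 30 cases with 7 lower (21 and 7 adjusted over the list alone; adjusted p = 6.97e-06). In control cells 9 of the 30 were higher and 17 lower, and the list was not called (9 and 17 adjusted over the list alone; adjusted p = 0.413). Macrophage markers were lower in 21 of 22 cases (21 adjusted over the list alone; adjusted p = 7.45e-06, and adjusted p = 0.0878 with an estimated correlation). Between day 7 and day 21 general epithelial markers were higher in 5 of 21 cases and lower in 10 (6 and 11 adjusted over the list alone; adjusted p = 0.286), and fibroblast markers higher in 4 of 22 and lower in 12 (4 and 12 adjusted over the list alone; adjusted p = 0.00765, and adjusted p = 0.441 with an estimated correlation). edgeR called 6947 genes higher and 7035 lower from day 0 to day 7, and 5362 higher and 6164 lower from day 7 to day 21. Scaling by library size alone moved the median log2 fold change of the first of these by 0.43 and gave 9479 higher and 5201 lower. For the second it gave 6052 higher and 4991 lower, and of the genes that changed at least 2-fold 2580 were higher and 476 lower.

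The difference between the roxadustat effects at 2 times was tested as an interaction. Between day 0 and day 7 it was called for 5418 genes, 2901 with a more positive effect at day 7 and 2517 with a more negative one. Lyz2 differed by -7.34 ± 0.14 (log2, SE; edgeR adjusted p = 1.06e-23), Ccl6 by -7.49 ± 0.20, the glycogen phosphorylase gene Pygl by 5.19 ± 0.15, the carbonic anhydrase gene Car12 by 4.47 ± 0.14 and Pdk1 by 4.02 ± 0.12. Of the macrophage markers 17 of 22 had a more negative and 1 a more positive effect at day 7 (17 and 1 adjusted over the list alone; camera adjusted p = 1.73e-44). Of the matrix genes 22 of 32 had a more negative and 3 a more positive one (25 and 3 adjusted over the list alone; adjusted p = 7.93e-21), and of the epithelial markers 19 of 21 had a more positive one (20 adjusted over the list alone; adjusted p = 4.16e-22). Between day 7 and day 21 the interaction was called for 8382 genes, 3919 more positive and 4463 more negative at day 21, and after scaling by library size alone 6504 and 2501 with a shift of the median of 0.28. Cemip, a hyaluronan-binding protein, differed by -5.76 ± 0.10 (edgeR adjusted p = 2.39e-25), Cped1 by -5.52 ± 0.10, Igfbp3 by -5.49 ± 0.11, the sphingosine phosphate exporter gene Spns2 by 4.03 ± 0.08 and the kidney amino acid transporter gene Slc6a18 by 6.62 ± 0.13. Epithelial markers had a more positive effect at day 21 in 19 of 21 cases (19 adjusted over the list alone; adjusted p = 5.13e-19) and fibroblast markers a more negative one in 18 of 22 with 2 more positive (18 and 2 adjusted over the list alone; adjusted p = 4.6e-14). Cell cycle genes had a more positive effect at day 21 in 35 of 38 cases with 2 more negative (35 and 2 adjusted over the list alone; adjusted p = 1.5e-08, and adjusted p = 0.186 with an estimated correlation).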

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

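All tests of explanations and all counts of other splits in this part were chosen only after the result was seen. Samples lying apart from the other 3 of their group were sought by the gap to the nearest sample as a part of the range. Of 196 groups of 4 values 5 had a gap beyond the critical value of the Dixon test, which chance exceeds in about 1 in 20. They are mt-Rnr2 in roxadustat day 7 replicate 4 as a share (0.566%, others 0.448 to 0.454%) and in CPM (5094, others 4054 to 4148), Cped1 in roxadustat day 21 replicate 1 (12.25 CPM, others 14.12 to 14.27), Flt1 in control day 7 replicate 4 (71.02 CPM, others 65.29 to 66.18) and Sfrp1 in control day 21 replicate 4 (294.3 CPM, others 268.5 to 270.2).

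The effect of roxadustat differed between day 0 and day 7 in 5418 genes by the interaction term, and the 5 with the smallest p were Lyz2 (-7.345), Ccl6 (-7.492), Pygl (5.193), Pdk1 (4.022) and Car12 (4.467, all log2). Between day 7 and day 21 it differed in 8382 genes, with the smallest p for Cemip (-5.756), Cped1 (-5.522), Igfbp3 (-5.493), Spns2 (4.029) and Slc6a18 (6.619). Day 0 compares fresh cells of injected and control mice and the later days compare cultures, so these differences combine time with the change from kidney to culture. They may also combine different kinds of exposure, since the labels do not say whether the cultured roxadustat cells came from injected mice.

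Epithelial markers were higher and fibroblast markers lower in roxadustat than control cells at day 21, and scaling of the libraries is argued against: over 4 scalings the medians of the epithelial list stayed between 5.18 and 5.51 and those of the fibroblast list between -3.56 and -3.21, the smallest in size being 3.21. For unchanged tubule cells carried over from the fresh isolate, the epithelial list would need 18% of the day 0 level. All 43 tubule markers lay below that, at a median of 0.279% of the needed level. The loss of tubule markers by day 7 in both arms had settled this already. It does not cover tubule cells that lost these markers in culture, which was not tested. A smaller share of fibroblasts with all other cells as before would raise macrophage markers too, but 17 of 22 were lower. At day 7 17 of 22 were lower already, so this argues only against a smaller share of fibroblasts as the sole change. A smaller share of fibroblasts beside a loss of macrophages is not excluded. From day 7 to day 21 the epithelial list changed by a median of -0.258 in roxadustat cells (SD of its members 0.79) and of -4 in control cells. This argues against a rising share of epithelial RNA in roxadustat cells as the reason why its roxadustat effect grew by 4.04. Levels are shares of a library, so growth of epithelial cells at the pace of the other cells with roxadustat is not excluded. A loss of epithelial cells from control cultures alone, or a change of gene expression within the same cells, may each give this pattern and was not tested.

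Matrix genes were higher in roxadustat than control cells at day 0. RNA of the cultured libraries would need 3.35% of the culture level, and 14 of 18 genes abundant in culture and scarce in fresh control cells lay below that, while a first form of this test on all 106 genes abundant in culture had found only 8 below by 2 SD and was replaced after that was seen by 1 on the 18 genes that fresh control cells have below the needed level. 1 deviating day 0 library is argued against by the list's call without each of the 4 libraries, with 12 or more matrix genes higher. More fibroblasts of an unchanged kind stays open. In the fit to the day 0 libraries alone 6 of 19 fibroblast markers had an upper bound under the median of all 32 matrix genes (1.00, log2). Without 4 that other kidney cells also make it was 3 of 15. Both sets include Col1a1, Col1a2 and Col3a1 (2.55, 2.61 and 3.15), none of them below, which favours this outcome. An earlier form against these 3 collagen genes, with the narrower bounds of all 20 libraries, had put 12 of 19 below. Its 19 markers were another set, without these collagen genes. Activation of fibroblasts in the injected mice may give the pattern as well, on 2 libraries against 2.

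H2-Ab1 was higher in roxadustat than control cells at day 7 and day 21, at 27.98 and 21.74 CPM. Antigen presenting cells in their day 0 make-up are argued against: at the shares that H2-Ab1 gives, 59.7% and 46.4% of the day 0 level, all 6 values of H2-Aa, H2-Eb1 and Cd74 lay below the needed level. Reads of a neighbouring gene are argued against by the highest level of H2-Aa and H2-Ob, 0.112 CPM. Transcription of H2-Ab1 alone, or of a transcript that overlaps it, may remain as an explanation, which counts per gene cannot resolve.

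Other splits of the libraries into groups were counted for 4 results. For roxadustat against control at day 7 (8926 genes) and day 21 (11781) and for day 21 against day 7 in control (12877) and roxadustat cells (11526), 1 of 35 splits, the real one, gave as many genes, and the highest other gave 0. For independent libraries chance would put the real split highest in 1 of 35 cases, the least that these splits can reach. A mixed split moves the real difference into the spread, so the 0 of the others adds nothing to that. Chance between animals or cultures is not covered, since the labels do not say what the replicates are. The overlap of day 7 and day 21 (5887 genes) was reached by 1 of 50 joint splits, with a highest other of 0, but this adds nothing, since other splits of either day call no gene. The interaction of day 21 with day 7 (8382 genes) was reached by 1 of 50, but a split that kept the real groups at 1 of the days gave 7857 genes, so these splits do not test whether the effect differs between the days. Comparisons with day 0 have 2 libraries in a group and were not split.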

How the results depend on the processing

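Leaving out mitochondrial and structural RNA genes, leaving out pairs of control day 21 replicates and leaving out day 0 libraries in the list tests were chosen only after the data were seen. With a fold of at least 2 the counts were 331 at day 0, 2485 at day 7 and 5278 at day 21 for roxadustat, 9317 and 5527 for day 7 against day 0 and day 21 against day 7 in control cells, 8728 and 3056 in roxadustat cells, 2155 and 3584 for the 2 interactions, and 1626 for the overlap of day 7 and day 21. The day 0 count of 1280 moved most. It was 610 at an adjusted p threshold of 0.01, 23 with only the day 0 libraries fitted, and 568 (without roxadustat replicate 1) to 1614 (without control replicate 1) with 1 library left out. In the other comparisons leaving out 1 library gave 8199 to 8540 (day 7), 11235 to 11578 (day 21), 13286 to 14127 and 12242 to 12699 (control cells), 12718 to 13824 and 10707 to 11267 (roxadustat cells) and 4471 to 5251 and 7934 to 8248 (interactions).

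Of 2321 alternative values for 142 named results 2276 kept direction and call. Most of these genes were picked from the same data by fold or p, which favours calls that hold. With only the groups compared 15 lost their call, all at day 0, with Col1a1 (2.55, adjusted p = 0.0556), Col1a2 (2.61, adjusted p = 0.152) and Col3a1 (3.15, adjusted p = 0.091) among them, at log2 fold changes about as large as before. Pdgfra at day 7 against day 0 in control cells was called lower without day 0 replicate 1 (-1.08) and higher without replicate 2 (0.56), the only named result called in both directions. With the replicate number as a replicate block all 142 were the same, and of 155 list results 5 lost and 6 gained a call. An estimated correlation ended the call of 35 of the 155 list results, and fry ended 2 and added 57. At day 0 the cell cycle list ranged from an adjusted p of 5.06e-10 (without control replicate 1) to 0.713 (without roxadustat replicate 1) and pointed lower without control replicate 2 (0.253). The list of cytokines and NF-kB targets was called lower without control replicate 1 (0.0127, and adjusted p = 0.0679 with an estimated correlation) and higher without control replicate 2 (0.000138, and adjusted p = 0.00987 with an estimated correlation), with 0.14 and 0.655 without roxadustat replicates 1 and 2. Control day 21 replicates form 2 close pairs. The squared difference over counting variance averaged 2.32 per gene between replicates 1 and 2 and 1.94 between 3 and 4. Between the pairs it was 16.1 to 22. Without replicates 1 and 2 the roxadustat count at day 21 was 10731 and without 3 and 4 it was 11496. These counts do not show whether the libraries within a pair are independent.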

Other observations

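All observations here were made after the data were seen, and no explanation was tested for them. Kap, a kidney androgen regulated gene of proximal tubules, was at 24600 CPM in fresh control and 35000 CPM in fresh roxadustat cells, so the Sca-1 sorted isolate held much tubule RNA, and levels of rarer cells at day 0 are shares of that mixture.

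Macrophage markers were higher with roxadustat at day 0 in 11 of 22 cases and lower in 17 of 22 at both later days. In control cells 14 of 22 were higher and 6 lower at day 7 than at day 0, and the list was not called (adjusted p = 0.712). Vegfa with roxadustat stood at 350, 334 and 352 CPM at the 3 times.

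Nuclear genes of oxidative phosphorylation were lower at day 21 than at day 7 in 39 of 41 cases in control (camera adjusted p = 0.000108, and 0.515 with an estimated correlation) and in 41 of 41 in roxadustat cells (adjusted p = 2.21e-14, and 0.319). The list of 2-oxoglutarate dioxygenases, the enzyme family that roxadustat acts on, leaves out the HIF prolyl hydroxylases themselves. It shares P4ha1 and other members with the HIF target list, so the results of these lists are not independent. Its members were higher with roxadustat at day 7 in 20 of 32 cases and lower in 4 (adjusted p = 3.2e-08), but at day 21 15 were higher and 11 lower (adjusted p = 0.676), and the effect was more negative at day 21 in 16 and more positive in 2 (adjusted p = 0.00197, and adjusted p = 0.0532 with an estimated correlation). The iron genes were higher at day 7 in 11 of 17 cases with 3 lower (adjusted p = 0.000877), and at day 21 in 8 with 6 lower (adjusted p = 0.0293, and adjusted p = 0.114 with an estimated correlation).

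Rn7sk and Rpph1, RNAs without a poly(A) tail, took 0.415% to 1.41% and 0.461% to 1.12% of counts in the 20 libraries, although the labels name an mRNA protocol, so selection of polyadenylated RNA was not complete or was not done.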
